A study of Rattus norvegicus with 8 samples.

How the data were processed

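RNA was measured by sequencing in dorsal root ganglia of 8 Sprague Dawley rat samples in 3 groups. Per the labels' protocols, ganglia were frozen in liquid nitrogen and ground, total RNA was taken up in TRIzol, and libraries followed a standard Illumina protocol. The submitters' processing notes name bcl2fastq, STAR 2.5.3a and DESeq2, without saying which step each served. The genome build, the gene annotation, the counting tool and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

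The authors deposited 2 tables, and both hold values per library on a log2 scale, as log2(normalized count + 1). One lists 4136 genes for IMQ against WT and the other 775 genes for lidocaine against IMQ. The scale was read from the values. Raised back to the linear scale, less 1, all values checked in every library (100% of those from 1 read up to 2000 reads, tolerance 0.02 reads) were whole multiples of 1 step per library. That step is what 1 read is worth after the authors' normalization. The IMQ values of genes in both tables differed by at most 4.98e-09, so the 8 libraries share 1 normalization. In both deposited tables the group means of each gene differed by at least 1.00 on the log2 scale, and genes below that size are not listed. What further test the authors applied is not stated in the tables, which give no fold change and no p-value. The tables are therefore selections of called genes, and levels of unlisted genes were not analysed here.

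Library totals were not used here, because a sum over listed genes is not a depth. The inverse of each step is the authors' normalization factor, taken here as relative depth. Differences in composition between libraries can also enter such a factor. Relative to the mean of the 8 libraries, WT libraries were at 1.09 to 1.34, IMQ libraries at 0.808 to 0.912 and lidocaine libraries at 0.789 to 0.873. No library was counted as a repeat of another. The median chi-square between 2 libraries of a group was at least 2.33 over genes with a mean of at least 50 reads, against 0.455 expected from counting alone. It was 28.7 to 134 between WT libraries, 2.33 to 6.60 between IMQ libraries and 8.29 between the lidocaine libraries. WT libraries thus differed most among themselves, while each fit below used 1 spread per gene for both groups.

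Groups were taken from the sample titles. Each comparison was tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(normalized count + 1) in the 2 groups of its table. Genes needed a mean normalized count of at least 1, a filter that removed none. Adjusted p-values are Benjamini-Hochberg values over the listed genes of a table, with a threshold of 0.05. Because every listed gene had already been called by the authors, these p-values say how evenly a difference ran through the libraries, and not how much of the transcriptome changed. Differences are on the log2(normalized count + 1) scale, which understates changes of low genes. The plan foresaw count tests as well, tied to raw counts. The deposited values are log2 values, so the planned count tests were not run. Reads recovered from these values were tested with limma-voom only, as an alternative added after seeing the data. The plan also foresaw 1 fit over all 3 groups only if 1 table held them. Lidocaine against WT was therefore tested only as an alternative chosen after seeing the data, on the 560 genes in both tables.

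Before the data were examined, 42 gene lists, the tests, the rule for named genes and the first set of alternatives were fixed. For each list with at least 5 listed members, a two-sided Fisher's exact test set the share of higher genes among its members against that among all other genes of the same table, with Benjamini-Hochberg adjustment over lists. This tests direction, not over-representation. It counts genes as independent, though members of a list can move together in the same libraries, so small p-values of lists overstate the support. Some genes stand in 2 lists, such as Socs3, Cfd and Cxcl1. Named genes are, per comparison, the 8 largest increases and 8 largest decreases among genes past the threshold with a symbol and a mean normalized count of at least 50, the 4 smallest adjusted p-values of each direction, the 4 smallest adjusted p-values in each list with at least 3 members past the threshold (2 for lists of 3 or 4 such members), and, for genes in both tables, 5 genes of each opposite order and up to 3 of each same order. The text prints part of these, and some named genes are not reported here. Other genes are named only where a group had 5 or fewer members or a gene was the exception in its list, and were chosen after their values were seen.

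Alternatives were a pseudocount of 0.1 or 10, no filter, an adjusted p under 0.01, a mean normalized count of at least 50, genes with a symbol only, the replicate number as a block, and each library left out in turn. Added after seeing the data were limma-voom on the recovered reads, counts as listed, and a two-sided Fisher's exact test of how often the IMQ-raised members of a list were listed as lower under lidocaine and passed. Opposite directions in the 2 comparisons were set against 1000 draws of unchanged groups with each gene's own spread. The limma step was tested on simulated negative binomial counts with 200 changed genes. For IMQ against WT (4136 genes) it recovered 88.8% of 4-fold and 21.2% of 2-fold changes, with 6.9% of calls false. For lidocaine against IMQ (775 genes) it recovered 92.9% of 4-fold and 62.0% of 2-fold changes, with 1.92% of calls false. Most simulated genes were unchanged, whereas the deposited tables hold only genes already called, so these rates do not carry over to them. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the rest. Gene symbols are those of the deposited tables. Of these, 3402 of 4136 and 649 of 775 are also symbols or synonyms in the RefSeq table of the rat assembly GRCr8, which served only for this check. No coordinates are given, since the authors' build is not known here.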

Results

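Dorsal root ganglia hold the cell bodies of the sensory neurons that serve skin, muscle and joints, with their satellite glia and resident immune cells. The study asked how gene expression in rat ganglia responds to imiquimod (IMQ), an agonist of Toll-like receptor 7 that is used on skin as a model of psoriasis, and to epidural lidocaine, a blocker of voltage-gated sodium channels. The WT group was untreated (n = 3). The IMQ group received imiquimod on the back skin for 6 days (n = 3). The lidocaine group received the same and in addition epidural 1% lidocaine for 4 days from day 3 (n = 2). Rats weighed 250 g and tissue was taken on day 7. Levels below are log2(normalized count + 1) as mean ± SD, and differences are between group means on that scale. The labels number the samples of a group but do not state that each came from a separate animal, so p-values measure the spread between these samples. Over the listed genes, libraries held 4311091 to 9035486 reads for IMQ against WT and 254922 to 778890 reads for lidocaine against IMQ.

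Ganglia of IMQ-treated rats carried far more immune transcripts than untreated ganglia. Igh-6 (ENSRNOG00000048402), the heavy chain of immunoglobulin M, rose most, from 3.44 ± 0.13 to 12.41 ± 0.46 (SD, n = 3 and 3), a 501-fold difference (8.97, SE 0.32, limma adjusted p = 3.26e-05). Complement C3 (ENSRNOG00000046834) rose 154-fold, from 7.13 ± 0.68 to 14.40 ± 0.25, and the B cell attractant Cxcl13 (ENSRNOG00000024899) rose 137-fold, from 5.19 ± 0.51 to 12.28 ± 0.54. Small nucleolar RNAs showed the largest decreases, with SNORD2 (ENSRNOG00000053621) at 9.16 ± 0.17 in WT and 1.84 ± 0.81 in IMQ. The table lists 2528 genes as higher and 1608 as lower in IMQ, and 2435 and 1530 of these passed limma's threshold.

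The other largest increases were Cxcl2 (8.31, SE 0.98), Heatr1 (7.93, SE 0.77), the protease inhibitor Slpi (7.67, SE 1.53), kininogen Kng1 (7.02, SE 0.80) and the chemokine Ccl20 (7.01, SE 0.66). Slpi varied widely among WT libraries (4.03 ± 3.55) and Cxcl2 among IMQ libraries (9.42 ± 1.95). Slfn4, Siglec1 and Csf2rb, the shared receptor subunit for granulocyte-macrophage colony-stimulating factor, interleukin 3 and interleukin 5, had the smallest adjusted p-values beside Igh-6, with increases of 5.31, 4.86 and 5.46 (SE 0.23, 0.24 and 0.27, limma adjusted p = 3.26e-05 each).

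Markers of several immune cell types rose together. All 29 listed genes of the macrophage and monocyte list (of 32 symbols) were higher and past the threshold, with a median difference of 3.00. They included the Fc receptor Fcgr2b (4.81, SE 0.24), the lysosomal protein Cd68 (3.79, SE 0.23) and lysozyme Lyz2 (3.70, SE 0.24). Of 20 listed lymphocyte genes, 19 rose, among them Cd8a of cytotoxic T cells (5.58, SE 0.32), Jchain and Mzb1 of antibody-secreting cells (4.69, SE 0.32, and 4.31, SE 0.39) and the pore-forming Prf1 (4.33, SE 0.45). The exception, the B cell receptor subunit Cd79a, fell by 1.22 (SE 0.46). All 13 listed neutrophil and marrow granulocyte genes were higher and 12 passed, with Csf3r at 4.73 (SE 0.32) and Cxcr2 at 5.44 (SE 0.37). Each of these lists leaned to higher values more than the rest of the table (two-sided Fisher's exact test, adjusted p = 4.5e-06, 0.00205 and 0.00509). Adjusted over the list alone, 29, 20 and 12 members passed. In every list of this comparison that number was the same as over all listed genes, except for skeletal muscle and for spinal cord glia, where it was 3 in place of 2. In the mast cell and eosinophil list the listed members were split, 2 higher and 4 lower, of which 5 passed (adjusted p = 0.241), and the mast cell proteases Mcpt1l1, Cma1 and Cpa3 fell by 2.22, 1.97 and 1.26.

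The interferon response list moved as a block. All 49 listed genes of 54 were higher and past the threshold, with a median of 2.52 (Fisher's exact test, adjusted p = 4.01e-10; 49 adjusted over the list alone). Irf7, a transcription factor that drives type I interferon genes, rose by 4.08 (SE 0.30), the antiviral Ifit1 by 4.43 (SE 0.35), Ifi47 by 3.71 (SE 0.28) and Oasl2 by 3.01 (SE 0.24). Genes of Toll-like receptor signalling were higher in 19 of 19 (adjusted p = 0.000434), with the co-receptor Cd14 at 3.05 (SE 0.28), Tlr2 at 3.09 (SE 0.29) and Tlr6 at 2.41 (SE 0.28). All 23 listed genes of antigen presentation rose (adjusted p = 5.16e-05). They included Ciita, the master regulator of class II genes (3.37, SE 0.37), RT1-Da (3.16, SE 0.31) and RT1-S3 (3.12, SE 0.25). RT1 genes are near-identical copies whose reads the counting could split, so single members are uncertain.

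Secreted inflammatory genes were also higher. Of 27 listed chemokines and chemokine receptors 26 rose (adjusted p = 0.000117), with Cxcl14 at 4.66 (SE 0.35) and Cxcl11 at 5.30 (SE 0.51); Ccl24 was listed at -1.10 and did not pass. In the list of the interleukin 23 and interleukin 17 axis and psoriasis cytokines, 19 of 20 listed genes were higher and 17 of these passed (adjusted p = 0.00205). Il1b reached 10.78 ± 1.19 from 5.03 ± 0.85 and Cxcl1 reached 8.98 ± 1.07 from 3.44 ± 0.30. Tnf was at 0 in all 3 WT libraries and at least 14.6-fold higher in IMQ, against a floor of 3 reads per library. Il36g went the other way and was at 0 in all 3 IMQ libraries. All 27 listed complement and acute phase genes rose (adjusted p = 1.22e-05), with C4a at 4.62 (SE 0.23), the endotoxin carrier Lbp at 5.99 (SE 0.37) and C2 at 4.01 (SE 0.26). C4a has a near-identical copy and its value is uncertain for that reason. Adjusted over the list alone, 26, 18 and 27 members of these lists passed.

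Glial and injury-related genes of the ganglion rose as well. In the nerve injury and regeneration list 17 of 18 listed genes rose (adjusted p = 0.00509), among them the secreted lectins Reg3b (35.5-fold, from 5.49 ± 0.56 to 10.64 ± 0.17) and Reg3a (4.93, SE 0.33), and the neuropeptide Vip (5.65, SE 0.69). Crh, corticotropin-releasing hormone, fell by 1.37. Gfap, an intermediate filament of reactive glia, rose 12.5-fold (3.65, SE 0.27), and 5 of 6 listed satellite glia genes were higher, with Glul at 1.41 (SE 0.28); this list did not differ in direction from the table (adjusted p = 0.43). Nrtn, a neurotrophic factor, fell by 3.65 (SE 0.64). Of 19 neuronal markers 3 were listed, all lower, with Sncg at 17.77 ± 0.68 in WT and 16.30 ± 0.10 in IMQ and Nefm at 18.67 ± 0.33 and 17.62 ± 0.02. Of 24 nociceptor genes 5 were listed. Tac1, the precursor of substance P, Calcb, Grik1 and Lpar3 fell by 1.04, 1.10, 1.14 and 1.41, and the opioid receptor Oprm1 rose by 2.41. Among 30 itch genes 4 were listed, with Nts (3.18, SE 0.48), Osmr (2.92) and Npr1 (1.29) higher and the receptor Mrgprb4 lower (-1.63, SE 0.24). Of the voltage-gated sodium channels, the targets of lidocaine, only Scn3a was listed, 1.89 higher.

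Genes of energy metabolism and translation stood at the lower end. All 66 listed nuclear genes of oxidative phosphorylation were lower and past the threshold (median -1.39, or -1.35 with 2 genes at 0 in IMQ set at their bound; Fisher's exact test, adjusted p = 1.05e-26), with Uqcrh at 13.77 ± 0.74 in WT and 11.48 ± 0.07 in IMQ. All 34 listed ribosomal protein genes were lower and 33 passed (median -1.26, adjusted p = 1.31e-13), with Rpl37 at -2.32 (SE 0.39). The WT libraries themselves differed in these genes. WT3 lay above WT1 in 100 of 100 of them, by a median of 1.5, and in 88.9% of all genes listed as lower. For the 3 listed neuronal markers the median of WT3 over WT1 was 1.31. Against WT1 alone, the median IMQ difference was -0.63 for oxidative phosphorylation and -0.41 for ribosomal proteins, and against WT3 alone it was -2.09 and -2.02. Of 42 listed small nucleolar, spliceosomal, 5S and 5.8S RNA genes, 37 were lower, with a median of -2.45. SNORD59 and SNORD81 fell by 6.64 (SE 0.43) and 4.75 (SE 0.36), and for this class the median difference between WT3 and WT1 was 0.23.

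Erythroid, skeletal muscle and keratinocyte genes were lower in IMQ. They also differed between WT libraries, with WT3 above WT1 by a median of 1.26 for erythroid, 1.32 for skeletal muscle and 0.78 for keratinocyte genes. All 12 listed erythroid genes fell (median -2.39, adjusted p = 4.82e-05), with Hbb at 15.75 ± 0.69 in WT and 12.63 ± 1.09 in IMQ; globin genes are near-identical copies and uncertain as single genes. All 20 listed skeletal muscle genes were lower and 18 passed, or 16 adjusted over the list alone (adjusted p = 4.2e-08), with Myh2 at -3.06 (SE 0.53), Tnnc2 at -4.64 (SE 1.23) and Pvalb, which sensory neurons also express, at -1.72 (SE 0.36). Of 11 listed keratinocyte genes 10 fell (adjusted p = 0.00146), with Krt14 at 7.07 ± 0.59 in WT and 1.30 ± 2.25 in IMQ. Of 11 listed bone and cartilage genes 6 rose and 5 fell (Fisher's exact test, adjusted p = 0.759). The cartilage collagens Col2a1 and Col11a2 fell by 2.26 and 2.65, while Prg4 rose by 3.28 (SE 0.32). Further large decreases were in Scand1 (-5.01, SE 0.46), Trnp1 (-4.03, SE 0.40) and Zfp771 (-3.87, SE 0.37). All 10 listed fibroblast and matrix genes rose (adjusted p = 0.0155), with Thbs2 at 3.00 (SE 0.33) and Fn1 at 2.18 (SE 0.34). All 9 listed endothelial genes rose too (adjusted p = 0.0227), with Eng at 1.73 (SE 0.23). Of the 29 lists tested, 14 leaned to higher and 5 to lower values. Without WT replicate 2, 1608 higher and 869 lower genes passed, and without IMQ replicate 3, 1563 and 892. The labels describe no vehicle on the skin of untreated rats.

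**Figure D1:**
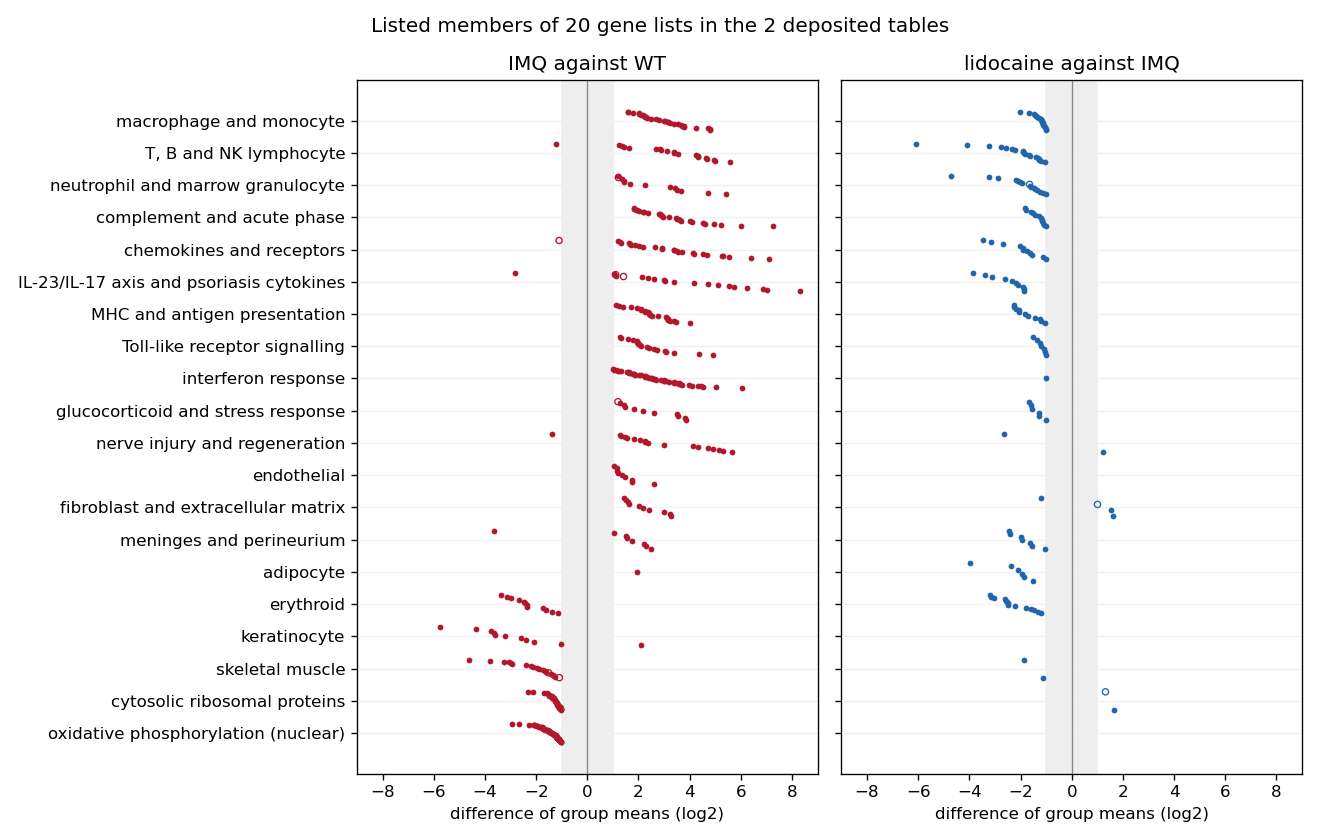
Difference of group means (log2, horizontal axis) of each listed member of 20 gene lists (vertical axis), for IMQ against WT (left, n = 3 and 3) and lidocaine against IMQ (right, n = 2 and 3). Filled points passed limma's threshold of 0.05, open points did not, and the grey band marks sizes under 1, which the tables do not hold; 49 interferon response genes lie to the right on the left side and 1 gene of that list appears on the right side.

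With epidural lidocaine added to imiquimod, antibody, macrophage, granulocyte and cytokine genes were lower than with imiquimod alone. Igh-6 fell 149-fold, from 12.41 ± 0.46 in IMQ to 5.19 ± 0.65 in lidocaine (SD, n = 3 and 2; -7.22, SE 0.38, limma adjusted p = 0.000175). Mzb1 fell by 6.08 (SE 0.34), Jchain by 4.09 (SE 0.42) and Pou2af1, a B cell transcription coactivator, by 3.69 (SE 0.33). C3 fell 3.44-fold, from 14.40 ± 0.25 to 12.62 ± 0.48. The table lists 702 genes as lower and 73 as higher under lidocaine, and 675 and 58 of these passed the threshold.

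Every listed member of the immune lists was lower. The macrophage and monocyte list had 18 of 18 past the threshold, with a median of -1.17, among them Clec10a (-1.67, SE 0.25), Fcgr2b (-1.48, SE 0.22), the integrin Itgb2 (-1.44, SE 0.22) and the mannose receptor Mrc1 (-1.37, SE 0.23). The lymphocyte list had 19 of 19, with a median of -1.86, and included the B cell gene Cd79b (-2.57, SE 0.42). Of 16 neutrophil and marrow granulocyte genes 15 passed, with Fcnb at -1.93 (SE 0.31) and Cxcr2 at -1.12 (SE 0.23). The median of the 16 genes was -1.65, and between IMQ2 and IMQ1 they differed by a median of -1.41. Cd177, another large decrease, was at 6.38 ± 0.55 in IMQ and 1.65 ± 2.34 in lidocaine. The interleukin 23 and interleukin 17 list had 10 of 10, with Il36b at -3.10 (SE 0.68) and Il24 at -2.32 (SE 0.58); its median was -2.25, the same as between IMQ2 and IMQ1. Chemokines and receptors had 11 of 11, with Cxcr6 at -3.15 (SE 0.37) and Ccr1 at -1.74 (SE 0.25). Cxcl2 fell by 3.84 (SE 1.06), a call that was lost without either lidocaine library. Antigen presentation had 11 of 11, with Ciita at -2.27 (SE 0.40) and RT1-DMa at -1.21 (SE 0.22). Complement and acute phase genes had 12 of 12, with Socs3, a feedback inhibitor of cytokine signalling, at -1.83 (SE 0.25) and Steap4 at -1.42 (SE 0.27). Adjusted over the list alone, 18, 19, 15, 10, 11, 11 and 12 members of these lists passed. All listed members of the 13 lists tested were lower, but so were 90.6% of all listed genes. Fisher's exact test could therefore not have shown a lean to lower values in lists of these sizes. By this test 0 lists passed after adjustment, and 0 had an unadjusted p under 0.05.

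Erythroid, adipocyte and meningeal genes were lower alongside the immune genes. All 14 listed erythroid genes fell (median -2.50; lidocaine2 above lidocaine1 by a median of 1.45), with the red cell anion exchanger Slc4a1 at -3.03 (SE 0.60) and Rhd at -2.61 (SE 0.45). All 6 listed adipocyte genes fell (median -2.02; lidocaine2 above lidocaine1 by a median of 1.02), with Fabp4 at -1.96 (SE 0.37), Plin1 at -2.08 (SE 0.53) and the adipokine Retn at -3.98 (SE 0.91). All 7 listed meningeal genes fell (median -1.96), with Slc47a1 at -2.44 (SE 0.40), Slc6a13 at -1.96 (SE 0.36) and Ptgds at -1.65 (SE 0.38). The metallothioneins Mt2A, Mt1m and Mt1 fell by 1.54, 1.61 and 1.28, as part of 6 of 6 glucocorticoid and stress genes. Gfap fell by 1.27 and Vip by 2.65. Further large decreases were in the lens chaperone Cryaa (-5.46, SE 0.69), in Mlc1 (-3.52, SE 0.39) and in the cartilage protein Chad (-3.21, SE 0.38). Of 24 nociceptor genes only Th, tyrosine hydroxylase, was listed, at 4.08 ± 0.58 in IMQ and 2.48 ± 0.51 in lidocaine, and of 30 itch genes only Npr1 (-1.19, SE 0.24); both passed. No gene of the pan-neuronal list and no sodium channel, potassium channel or oxidative phosphorylation gene was listed for this comparison, which shows only that none met the authors' selection.

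Few genes were higher under lidocaine, and their differences were less even. Tnn, tenascin N, was at 5.40 ± 0.68 in IMQ and 9.67 ± 2.82 in lidocaine (adjusted p = 0.0121). Of 4 listed fibroblast and matrix genes, periostin Postn (1.54, SE 0.54, adjusted p = 0.03) and Mmp3 (1.60, SE 0.61, adjusted p = 0.04) rose, Thbs1 fell by 1.20 (SE 0.30) and Col1a1, at 1.01, did not pass. Of 3 listed bone and cartilage genes, Mmp13 rose (1.24, SE 0.47, adjusted p = 0.0397), and Chad and Atp6v0d2 fell by 3.21 and 2.74. Rpl30 (1.64, SE 0.51), Gpr165 (2.20, SE 0.63), 7SK RNA (1.32, SE 0.49) and Crh (1.22, SE 0.44) also passed. Fam159b and Lrr1 were at 0 in all 3 IMQ libraries and at least 4.78-fold and 3.26-fold higher under lidocaine, against a floor of 3 reads per library. The calls of Gpr165, Mmp3, Mmp13, Rpl30, 7SK and Crh were lost without either lidocaine library, and that of Postn without lidocaine replicate 2. Without lidocaine replicate 1, 23 higher and 364 lower genes passed, in place of 58 and 675; without lidocaine replicate 2, 27 higher genes passed, and without IMQ replicate 3, 30 did. The labels describe no epidural injection without lidocaine, so the injection and the drug were not separated.

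The comparisons overlapped in 560 genes, and 532 passed the threshold in both. Of these, 496 were higher in IMQ than in WT and lower under lidocaine than in IMQ, 18 moved in the reverse order, 2 were higher in both and 16 were lower in both. Igh-6, Mzb1, Jchain and cathepsin E (Ctse) were of the first kind; Ctse was 1.70 higher in IMQ than in WT (SE 0.29) and fell by 2.31 under lidocaine (SE 0.27). Spdef and Epyc were lower in IMQ and higher under lidocaine, both at low levels. Postn and Mmp3 were higher in both. The erythroid gene Ahsp, the muscle gene Myl1 and the protease inhibitor Pi16 were lower in both. The IMQ libraries enter both comparisons with opposite signs, so opposite directions arise with no effect. In 1000 simulated draws of unchanged groups 64.7% of genes had opposite signs, and 92.7% did among simulated genes that differed at least 2-fold in both, against 95.9% observed over the 560 listed genes. The simulated share rests on a mean of 14.9 genes per draw, while all 560 listed genes have that size by selection, so it does not show how much of the pattern comes from the shared libraries. The 3 IMQ libraries cannot be split into parts of at least 2, so part of the excess over the simulated share may come from them, and the number expected from independent lists was not computed because the genes tested are not known here. Without lidocaine replicate 1, 303 genes had opposite directions in place of 514.

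The gene groups raised by IMQ were not equally often listed as lower under lidocaine. Of 2435 genes past the threshold and higher in IMQ, 496 (20.4%) were listed, past the threshold and lower under lidocaine. Genes not listed may have fallen by less than the limit of the table, and their values under lidocaine are not known here. In a two-sided Fisher's exact test chosen after seeing the data, over 20 lists, the share was 15 of 19 for lymphocyte genes (78.9%, adjusted p = 1.24e-06), 18 of 29 for macrophage genes (62.1%, adjusted p = 1.01e-05) and 9 of 12 for neutrophil and marrow granulocyte genes (75%, adjusted p = 0.00046). It was 1 of 49 for interferon response genes (2.04%, adjusted p = 0.00126), and that gene was Irf1, which fell by 1.02. Antigen presentation (11 of 23), complement and acute phase (12 of 27), meningeal (5 of 7) and glucocorticoid (6 of 10) genes also had raised shares, with adjusted p = 0.0111, 0.0169, 0.0167 and 0.0172, as did the interleukin 23 and interleukin 17 list (8 of 17, adjusted p = 0.0265). With each of the 8 libraries left out in turn, the lymphocyte and interferon calls held in 8 of 8 fits, at 63.2% to 78.9% and 0% to 2.08%. The macrophage call was lost without IMQ replicate 3 (41.4%). The neutrophil, antigen presentation and glucocorticoid calls held in 3 fits each, the complement call in 5, the meningeal call in 4 and the interleukin 23 and interleukin 17 call in 1, with 11.8% without either lidocaine library. At an adjusted p under 0.01 the interferon call held (0%), and the other 8 were lost, with shares of 42.9% for lymphocyte, 39.3% for macrophage and 42.9% for neutrophil genes. The share for nerve injury genes was 1 of 17 and for endothelial genes 0 of 9, neither different from the rest (adjusted p = 0.343 each). Genes were not matched for the size of their rise in IMQ. Listed members differed from WT by a median of 3.40 in the lymphocyte, 3.00 in the macrophage and 2.27 in the neutrophil list. That median was 2.52 in the interferon list and 1.89 over all genes listed as higher. The test also counts genes as independent, though members of a list can move together in the same libraries.

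Genes that rose with IMQ and were lower under lidocaine were also set against their untreated level. Among the 514 genes listed as higher in IMQ and lower under lidocaine, the lidocaine mean lay above the WT mean in 413, below it in 87 and at the same value in 14. Slc6a16 was among these 14 and stood at 0 in all WT and lidocaine libraries, so an equal value can mean that no read was counted. In 1 limma fit of all 3 groups, chosen after seeing the data, 207 of the 514 were past the threshold and higher in lidocaine than in WT and 7 lower. C3 was 5.49 above WT (SE 0.41, adjusted p = 2.49e-05), Cd8a 4.27 above (SE 0.30), Fcgr2b 3.33 above (SE 0.23) and Gfap 2.38 above (SE 0.32). Igh-6 was 1.75 above WT (SE 0.37, adjusted p = 0.00422), Jchain differed by 0.60 (SE 0.45, adjusted p = 0.323) and Mzb1 differed by -1.77 (SE 0.46, adjusted p = 0.0114). Meningeal genes such as Slc47a1 (-0.15, SE 0.42) and Aldh1a2 (0.08, SE 0.53) did not differ detectably from WT. Erythroid Ahsp differed from WT by -3.94 (SE 0.45, adjusted p = 0.000148). Over the 514 genes, the median share of the IMQ difference left under lidocaine was 38.1%, with quartiles of 9.07% and 57.6%. These genes were selected for a fall of at least 1.00 from the same IMQ libraries, which lowers that share by construction. It does not cover the other genes raised by IMQ, most of which have no value under lidocaine here.

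**Figure D2:**
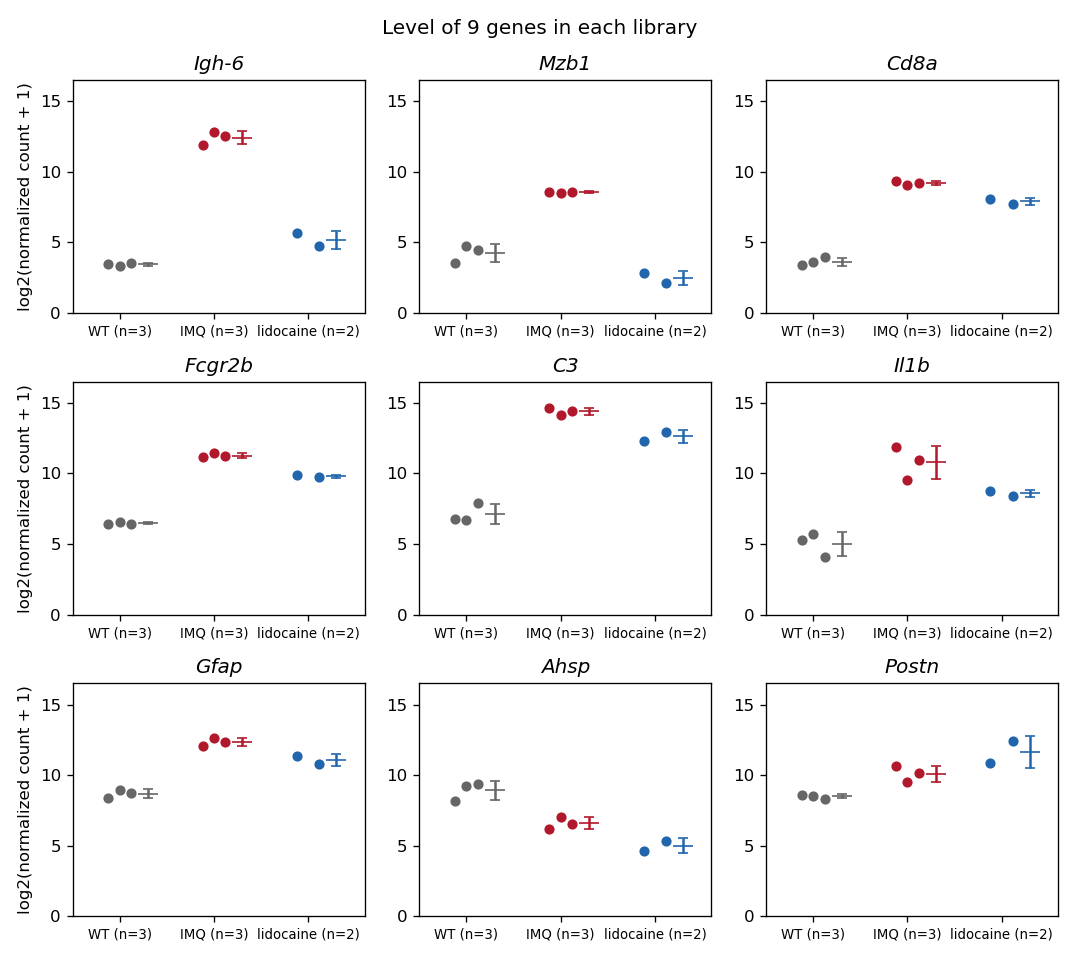
Level of 9 genes as log2(normalized count + 1) (vertical axis) in each library of the 3 groups (horizontal axis), with the mean and SD beside the points. Igh-6 stands at 3.44 in WT, 12.41 in IMQ and 5.19 in lidocaine, Ahsp at 8.93, 6.58 and 4.99, and Postn at 8.50, 10.09 and 11.64.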

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

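Tests named as added were chosen after seeing the data. Of the 151 named results for IMQ against WT and the 82 for lidocaine against IMQ, 0 changed direction under any alternative run; 16 and 34 of these genes lost their call under at least 1 alternative. At an adjusted p under 0.01, 1276 higher and 619 lower genes passed for IMQ against WT (1895 in all), 18 higher and 336 lower for lidocaine against IMQ (354 in all), and 240 genes had opposite directions in both, fewer by construction. With a mean normalized count of at least 50, 12 higher and 437 lower genes (449) passed for lidocaine against IMQ, again by construction. Leaving out 1 library in turn gave 2455 to 3949 genes for IMQ against WT (1563 to 2397 higher, 869 to 1552 lower), 387 to 694 for lidocaine against IMQ (23 to 50 higher, 364 to 644 lower) and 303 to 503 genes of opposite direction. Fewer samples account for part of this; why single libraries differ was not tested. For lidocaine against WT these fits (added) gave 146 to 217 higher and 24 to 36 lower genes. A left-out lidocaine library leaves 1, which is then assumed to vary like the IMQ libraries. Pseudocounts of 0.1 and 10 gave 3786 and 3983 genes for IMQ against WT and 701 and 746 for lidocaine against IMQ. Limma-voom on the recovered reads (added) gave 3975 and 726.

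The share of IMQ-raised genes of the interleukin 23 and interleukin 17 list that were listed as lower under lidocaine and passed (added) was 8 of 17, or 47.1%, with an adjusted p of 0.0265. It fell below that of the other genes at an adjusted p under 0.01 (5.88%) and without either lidocaine library (11.8% each), and the cause was not tested. The lists with a direction call numbered 19 for IMQ against WT and 13 at an adjusted p under 0.01. They numbered 18 at a mean normalized count of at least 50, and 18 over the genes that passed with the replicate block.

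With the replicate block, 3818 genes passed for IMQ against WT and 600 for lidocaine against IMQ, of which 37 were higher and 563 lower, and 419 genes had opposite directions. The labels do not say that equal numbers share a day or litter. Deviations of same-numbered WT and IMQ libraries correlated at -0.16, -0.06 and -0.12 across genes, and none of these libraries correlated best with its own number. Between IMQ and lidocaine the values were 0.0163 and 0.044. The numbers are not treated as pairing.

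The 2-fold limit and the filter on low values removed no gene and test nothing. The planned edgeR count test, upper-quartile factors, count filter and estimated correlation were not run. The plan tied the count test to files of raw counts and the estimated correlation to a table of all genes tested. The files hold log2 values of called genes only, and reads recovered from them were tested with the added limma-voom fit. The 2-group fit is the one reported. Depth limits low genes, since 1186 of 4136 and 313 of 775 genes had a mean normalized count under 50.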

Other observations

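Several further lists had few listed members in IMQ against WT. Clock genes moved in both directions, with the output gene Dbp at -1.83 (SE 0.25, limma adjusted p = 0.00119) and Npas2, Bhlhe40 and Arntl at 2.11, 1.22 and 1.12. Of 11 axon guidance genes 10 rose, with Sema3a at 2.90 (SE 0.46) and Sema6a at 3.01 (SE 0.67), a direction that missed the threshold (two-sided Fisher's exact test, adjusted p = 0.0824). All 7 listed calcium, TRP, P2X and Piezo channel genes rose, with Trpv4 at 2.19 (SE 0.30), Piezo1 at 1.53 (SE 0.22) and P2rx7 at 2.18 (SE 0.70; adjusted p of the list 0.0693). Of 6 potassium channel genes 4 fell, led by Kcnn1 (-1.66, SE 0.27), and Kcnj2 rose by 3.47 (SE 0.69). All 9 immediate early genes rose (adjusted p = 0.0227), with Atf3, a marker of injured neurons, at 2.39 (SE 0.33).

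The tests of explanations in the next 3 paragraphs were chosen after the results were seen; the lists they use were fixed before, except the class of small RNAs, which was set after the tables were seen. Genes of oxidative phosphorylation, ribosomal proteins and small RNAs were lower in IMQ than in WT. The listed small RNAs had a median difference of -2.45, with an upper quartile of -1.76. Both lie beyond -1.46, the largest fall among the 3 of 19 neuronal markers that were listed (Sncg). For the listed small RNAs this argues against dilution of ganglion cells by cells that entered as the only cause. Small RNAs that differed by less than 1.00 are not listed, so the class as a whole was not tested. For oxidative phosphorylation and ribosomal genes, a difference between libraries that is not tied to treatment is a candidate explanation, since WT3 exceeded WT1 by a median of 1.5 with the same sign in 100 of 100 genes, about as much as IMQ and WT differed (-1.32). An effect of imiquimod (median -1.39 for oxidative phosphorylation) cannot be told apart from a difference in library preparation, because the labels give no batch.

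Immune genes were lower in lidocaine than in IMQ. Noise in the IMQ libraries that is independent from gene to gene would make about as many listed genes lower as higher. With 90.6% lower, the values argue against such noise as the cause. Variation that moves many genes of a library together could give such a share, so the share says nothing against it. Less tissue from around the ganglion in the lidocaine samples may account for part of the pattern. All 27 listed erythroid, adipocyte and meningeal genes were lower. Set against the other listed genes, this share gave p = 0.0998 (two-sided Fisher's exact test). It is the highest share possible, so the test could not have shown a raised share and decides nothing. Other lists of surrounding tissue had few members. Of these, 2 of 2 skeletal muscle and 2 of 3 bone and cartilage genes were lower, but 3 of 4 fibroblast and matrix genes were higher. No endothelial, pericyte and smooth muscle or keratinocyte gene was listed. Between IMQ2 and IMQ1 the median difference was 1.10 in erythroid, -1.15 in adipocyte and -0.85 in meningeal genes. It was 0.13 in macrophage and -0.13 in lymphocyte genes, but -1.41 in neutrophil and 1.04 in antigen presentation genes. Macrophage and lymphocyte genes thus followed none of the 3 surrounding lists there. Those lists moved in opposite directions, so these values do not decide the question. An effect of lidocaine on the 675 lower genes cannot be told apart from less surrounding tissue with 2 lidocaine libraries.

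For IMQ against WT, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 3965 genes, and the highest of the others gave 3. With 10 splits a share under 0.05 cannot be reached, and the listed genes had been selected on the real split.

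Libraries within a group differed along common axes. Over genes with a mean normalized count of at least 1000, WT2 lay between the other WT libraries in 92.0% of 867 genes, and IMQ3 lay between the other IMQ libraries in 55.2% of 1038 genes of the first table and 87.0% of 123 of the second, where chance gives 33.3%. Across the 4136 genes, which are not independent replicates, the difference of WT1 from WT3 correlated at 0.47 with the difference of IMQ from WT2, which shares no library with it. Among genes lower under lidocaine, IMQ2 exceeded IMQ1 by a median of 1.10 in 14 erythroid genes and lay below it by a median of -2.25 in 10 interleukin 23 and interleukin 17 genes, with 0.13 in 18 macrophage and -0.13 in 19 lymphocyte genes. The same median was -1.41 in 16 neutrophil and marrow granulocyte, -1.15 in 6 adipocyte, -0.85 in 7 meningeal and 1.04 in 11 antigen presentation genes. Between lidocaine2 and lidocaine1 the median difference was 1.45 in the erythroid, 1.02 in the adipocyte, 0.45 in the macrophage, 0.31 in the meningeal, 0.20 in the neutrophil, 0.02 in the interleukin 23 and interleukin 17, -0.19 in the lymphocyte and -0.29 in the antigen presentation genes.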
